A study of Mus musculus with 38 samples.

How the data were processed

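Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 6 histone modifications in livers of male and female CD-1 mice, an outbred stock, at 8 weeks of age. The marks were H3K4me1, H3K4me3 and H3K27ac, which lie at promoters and enhancers, H3K36me3, which lies over transcribed gene bodies, and H3K27me3 and H3K9me3, which lie over silent chromatin. The labels list 34 histone libraries and 4 libraries made with control IgG. They give 4 male and 3 female libraries for H3K4me1 and H3K4me3, 3 of each sex for H3K27ac and H3K27me3, and 2 of each sex for H3K36me3 and H3K9me3. The sample titles carry codes of unstated meaning, of which the male and female libraries share 2 for each mark except H3K27me3, where they share 0. Nothing in the labels says whether the libraries of different marks came from the same animals.

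The deposited peak files were identical byte for byte across the libraries of a mark and sex, so each of the 12 mark and sex combinations was used as 1 list made from pooled libraries. A list of this kind has no spread between replicates. No test between animals was therefore run, and shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. All lists hold peaks on the 19 autosomes, and the sex chromosomes were not analysed here for any mark. Of the 4 IgG libraries, 1 male library had a file of aligned reads. It belongs to an earlier record than the other IgG libraries, and no age was taken from its labels. The other IgG libraries were not analysed here.

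Genome build mm9, Bowtie and SICER 1.1 are named in the submitters' processing notes, and all coordinates are mm9. Per the labels, SICER used windows of 400 bp and gaps of 2400 bp for H3K27me3 and H3K9me3, and windows of 200 bp and gaps of 800 bp for H3K36me3. The column names of the H3K4me1, H3K4me3 and H3K27ac lists are those of MACS peaks, and the version of that caller is not given in the sources used here. The read counts in islands and the tag counts in peaks are raw whole numbers deposited by the authors. In each H3K27ac list, the tags of 17335 peaks and the scores of 10875 were written with 3 significant digits and the others in full, so read totals for this mark, and ranks by score within it, are approximate. Per the file headers, each SICER island also has control reads, a p-value and a fold change over control. The fold ratio deposited for an island equals its reads over control reads times 1 constant per list. Each MACS-type peak has a fold enrichment, a false discovery rate in percent and a score of minus 10 times the log10 p-value, per the file headers. These peak scores are the authors' own and were used only to rank peaks within a list. The islands of equal coordinates in both sexes had equal control reads in 316 of 316 H3K36me3, 129 of 129 H3K27me3 and 63 of 63 H3K9me3 cases, so each pair of lists shared its control.

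Every peak also carries a log2 ratio of male over female signal, a p-value for the sex comparison and a call (male, female or sex-independent), all from the authors' deposited table. How those ratios were normalised is not given in the sources used here. For all 384017 peaks the call equals the rule of an absolute log2 ratio of at least 1 with a p below 0.001. These p-values compare pooled libraries and do not measure variation between animals.

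A peak was named sex-only when no peak of the same mark in the other sex overlapped it by 1 bp or more. Overlapping peaks of both lists were merged into regions, and a region was male-biased or female-biased when it held calls in that direction alone. Overlap between marks was compared with 200 redraws of the same number of peaks from the same list, matched on chromosome and on 10 width classes, and is given as a percentile that describes these lists. Called peaks of the 4 active marks (H3K4me1, H3K4me3, H3K27ac and H3K36me3) lying within 25 kb of each other were joined into domains. Peaks of both lists entered, so a site called in the male and in the female list counts once per list. A domain was male-active or female-active when at least 3 active marks had calls in that direction alone. Joining was first explored with calls of all 6 marks, and the definition on active marks alone was fixed after those results had been seen. The repressive marks were measured over them afterwards and compared with 200 random placements of equal widths on the same chromosome. The nearness of domains to each other was compared with 200 draws from all domains, a test chosen after the groups were seen.

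The IgG file holds 11201113 reads of 35 bases, of which 37.2% lie at a position and strand already seen. Reads per kb were divided by the autosomal mean of 4.38 reads per kb to give a relative IgG density. GC content was taken from the sequences of the IgG reads in a region and, for peaks, within 1 kb of it.

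Named regions followed a rule fixed before the data were examined, the 5 sex-only peaks with the best own-list score per mark and sex. Any other region was chosen after its values were seen, including all domains. Regions carry no gene names, because no mm9 annotation was used here. For that reason the planned comparisons of marks at genes, gene lists, cell type markers and gene states were not run, and neither was the share of peaks on the X chromosome. States were described at H3K4me3 peaks in their place. Alternatives covered the overlap that counts as shared, the peak threshold, merging of peaks within 1 kb, removal of the top 1% of 10 kb windows by IgG reads, the centre of the ratios and their relation to GC content, and the gap and number of marks that define a domain.

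The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Sex-only counts equalled those of bedtools 2.31.1 in 12 of 12 lists. The overlap code was also tested on simulated data with H3K27ac peak widths, where it recovered 1000 of 1000 planted sex-only peaks and misnamed 0 of 19000 shared peaks. Of 100 simulated sets with no enrichment, 5 fell outside the middle 95% of redraws.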

Results

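Livers of male and female mice were compared for 6 histone marks, to find where chromatin differs between the sexes. Each mark gave 1 pooled peak list per sex, from 2 to 4 libraries, so no value below has a spread between animals. Reads inside peaks, which depend on enrichment and covered length as well as depth, numbered 12562838 in the male and 20459697 in the female list for H3K4me1, 5087982 and 5084261 for H3K4me3, 19253391 and 12837285 for H3K27ac, 14557426 and 12881429 for H3K36me3, and 15305301 and 16904292 for H3K27me3. H3K9me3 had the fewest, with 1526754 reads in male and 2490730 in female islands.

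The marks covered very different amounts of the autosomes, and far more so than the sexes did. H3K27me3 covered 565 Mb in males and 579 Mb in females, in 20048 and 19506 islands with a median width of 21600 bp in either list. H3K36me3 covered 309 and 317 Mb in 25517 male and 19057 female islands, so the male list was made of more and shorter pieces (median 6800 against 10800 bp). H3K4me1 gave 74275 male and 82944 female peaks, H3K27ac 40903 and 38306, and H3K4me3 16018 and 18942. H3K9me3 showed the widest gap between the sexes, with 10875 male islands over 176 Mb and 17626 female islands over 223 Mb. The female H3K9me3 list also held more reads inside islands.

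Most peaks of every mark except female H3K9me3 had a partner in the other sex. H3K4me3 was the most shared promoter mark in males, with 1435 male-only peaks (8.96%, 95% interval 8.52 to 9.41), against 3485 female-only peaks (18.4%, 17.85 to 18.96). For H3K4me1 the counts were 11266 male-only (15.2%) and 23542 female-only peaks (28.4%). H3K27ac went the other way, with 8688 male-only (21.2%) and 4451 female-only peaks (11.6%), and so did H3K36me3, with 4900 (19.2%) and 1332 (6.99%). H3K27me3 was even, at 3911 (19.5%) and 4139 (21.2%). For H3K9me3, 4240 male islands (38.99%) and 10624 female islands (60.3%) had no partner.

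**Figure D1:**
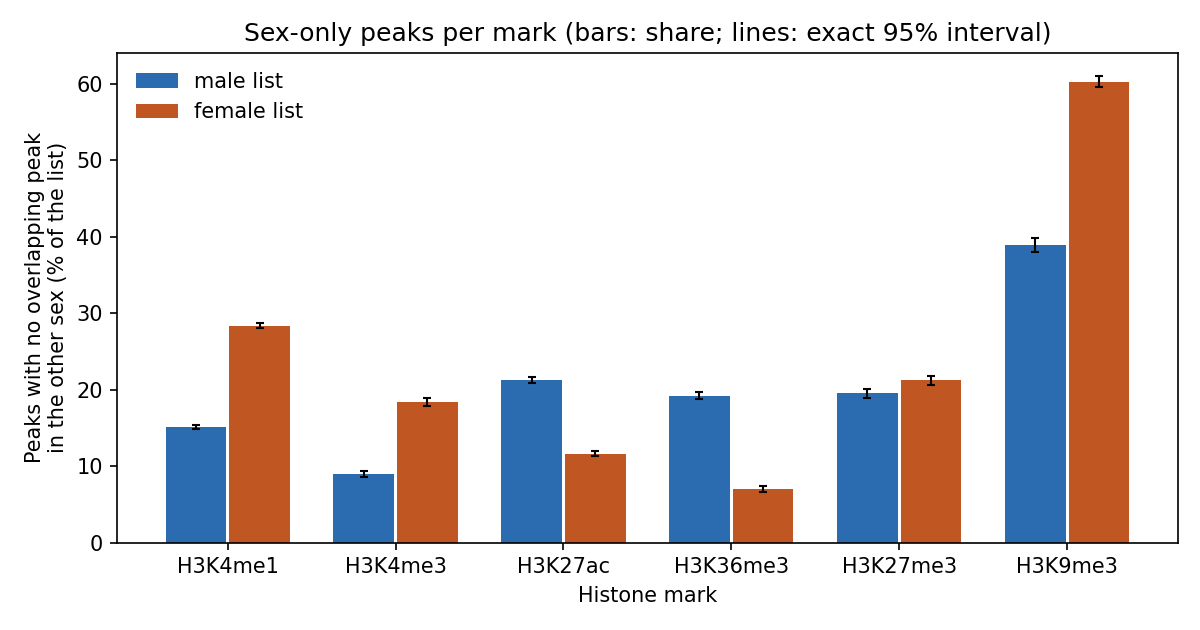
Share of the peaks of each list (vertical axis, percent) with no overlapping peak of the same mark in the other sex, for the 6 marks (horizontal axis), with the male list in blue and the female list in orange. Lines are exact 95% intervals, which cover counting error only. Shares run from 6.99% for female H3K36me3 to 60.3% for female H3K9me3.

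Sex-only peaks of most marks sat towards the weak end of their lists. Their median rank was at the 91.0 percentile of the male H3K4me3 list (100 being the weakest), against 45.5 for shared peaks, and at 80.4 against 43.7 in the male H3K4me1 list. Sex-only H3K9me3 islands were spread more widely, with median ranks at 62.1 in males and 60 in females, and 1534 of 4240 and 4170 of 10624 lay in the better-scoring 50%. They were also narrower, with a median of 867 bp against 1896 bp for male H3K4me3. Among the better-scoring 50% of male H3K4me3 peaks, 4 had no partner anywhere in the female list, and 26 of the better-scoring 50% of female peaks had none in the male list. The 4 male peaks lie at chromosome 3, 138039471 to 138044047, chromosome 19, 23135714 to 23139429, chromosome 17, 44207107 to 44209072, and chromosome 15, 4676837 to 4680616. They are also the first 4 of the 5 male-only H3K4me3 peaks named by the fixed rule. Which sex had more sex-only peaks depended on list length for some marks. With the longer list of each pair shortened to the length of the shorter, H3K4me3 had 2018 male-only and 1356 female-only peaks, H3K36me3 had 1900 and 3294, and H3K9me3 had 5618 and 5508.

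Quantitative calls gave a different picture from presence and absence. In the authors' deposited table, merged H3K4me1 regions were male-biased in 6412 cases and female-biased in 3406, out of 88686. For H3K4me3 the authors' deposited table gave 780 male-biased and 244 female-biased regions out of 19153, although the female list had more sex-only peaks. H3K27ac was the active mark with more female calls in the authors' deposited table, 1220 against 772 of 43542 regions (38.8% male). H3K27ac was nearly even after the correction for GC content described below. Ratios from the authors' deposited table then gave 1029 female-biased and 940 male-biased regions (47.7% male). That correction also takes out any offset of shared peaks. Centring these ratios on shared regions, without GC content, gave 1088 and 893 (45.1% male), and they showed little relation with GC content. H3K36me3 had 142 male-biased and 86 female-biased regions, and H3K9me3 had 373 and 396, per the authors' deposited table. The same correction left 183 male-biased and 212 female-biased H3K9me3 regions in ratios from the authors' deposited table, and centring alone left 367 and 404. The line was fitted in each list on its shared peaks. Their median log2 in the authors' deposited table was 0.11 in the male and -0.13 in the female H3K9me3 list. The part of GC content in this drop was therefore not separated from list offsets. The split was most uneven for H3K27me3, where the authors' deposited table called 162 regions male and 8 female (95.3% male, 95% interval 90.9 to 97.9). The share of sex-only peaks with a call of their own sex in the authors' deposited table ran from 0.145% of female-only H3K27me3 islands to 33.8% of male-only H3K4me3 and 43.5% of male-only H3K4me1 peaks. Of the male-only H3K27ac peaks, 28.6% had a ratio towards the female side in the authors' deposited table. The H3K4me1 split was sensitive to the centre of the ratios and to GC content. Male calls made up 65.3% of biased regions as deposited and 59.0% (5651 male and 3922 female) after centring on shared regions. They made up 53.6% (4105 male and 3558 female) after a straight-line correction of the ratios for GC content, which also takes out an offset. Both alternatives were chosen after seeing the data.

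Sex differences of the active marks coincided in a limited number of places, all of them found after the data were seen. The called peaks of both lists formed 8182 domains, of which 5276 held 1 called peak. At least 3 active marks were called in the same direction, with no call the other way among those marks, in 69 male-active and 57 female-active domains, and all 4 marks in 14 and 12 of them. Of the 57 female-active domains, 19 lay within 1 Mb of another, in 7 groups, against a median of 4 and a highest value of 13 among 200 draws of as many domains per chromosome from all 8182. Of the 69 male-active domains, 8 did so, in 4 groups, within the range of their draws (median 4, highest 15). The largest group, on chromosome 7 from 26676089 to 27739245, held 6 female-active domains with 94 called peaks. A second group on chromosome 5, from 146214847 to 146617984, held 3 domains, and chromosome 19 had a pair of female-active domains between 39575861 and 40080199 and another pair between 7838944 and 7986999.

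H3K27me3 over the female-active domains was biased towards males. A male H3K27me3 call lay in 23 of the 57 female-active domains (40.4%, 95% interval 27.6 to 54.2), against a median of 0 and a highest value of 2 among 200 random placements. Some of the 23 were neighbours, with 5 of the 6 domains of the chromosome 7 group among them. The interval and the placements treat neighbouring domains as independent, so the interval may be too narrow. The share depended on the definition: with at least 2 active marks it was 42 of 365 domains (11.5%, 8.42 to 15.2). In the 34 of these domains that held any H3K27me3 island, the mean ratio in the authors' deposited table was above 0 in 34, with a median log2 of 1.465. Of the 69 male-active domains, 1 held a female H3K27me3 call (highest random placement 0). Only 8 female-biased H3K27me3 regions exist against 162 male-biased ones, so few could be met. Of these domains, 59 held no H3K27me3 island in either sex. In the 10 with such islands, the median log2 in the authors' deposited table was -0.35, with 8 below 0. H3K9me3 calls were few at both kinds of domain, with a male call in 2 and a female call in 1 of the female-active domains, and a female call in 2 of the male-active ones. In the 16 male-active domains with H3K9me3 islands, the median log2 in the authors' deposited table was -0.74, with 14 below 0. In the 11 female-active domains with such islands it was 0.13, with 7 above and 4 below 0, per the authors' deposited table.

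**Figure D2:**
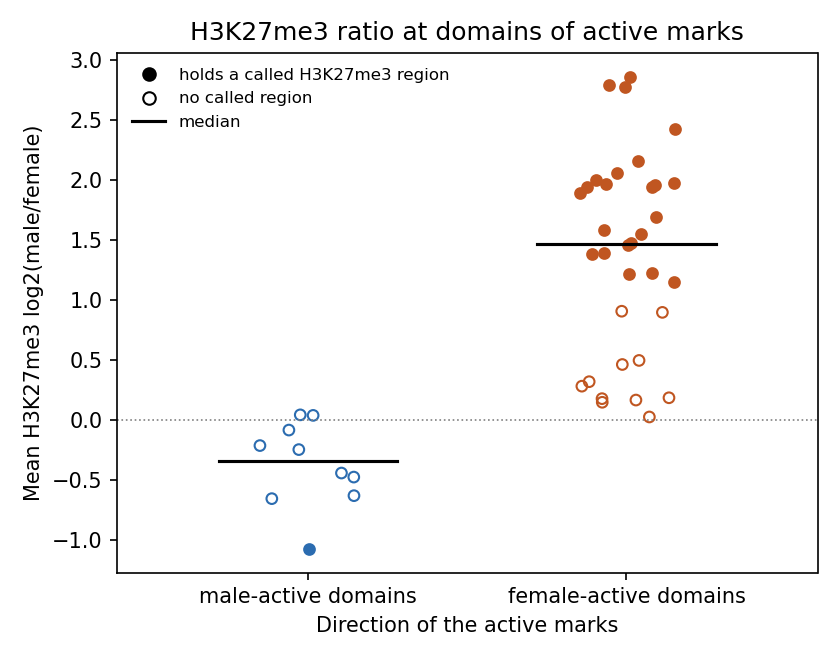
Mean H3K27me3 log2 ratio of male over female (vertical axis) over each domain of active marks that holds H3K27me3 islands, for the 10 male-active (blue) and 34 female-active (orange) domains. Each point is a domain, filled where it holds a called H3K27me3 region, and the lines are medians, at -0.35 and 1.465.

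The chromosome 7 group shows the arrangement in detail. Chromosome 7 from 26838538 to 26926192 held a female-active domain of 87.7 kb. Counted over both lists, 11 H3K4me1, 2 H3K4me3, 14 H3K27ac and 2 H3K36me3 peaks in this domain were called, all female. Over it lay a male H3K27me3 island, from 26855200 to 26899599, with a log2 ratio of 2.86 in the authors' deposited table and no island in the female list. The neighbouring domain, from 26958097 to 27009563, had a female-only H3K4me3 peak at 26958376 to 26961818, with a log2 of -3.17 in the authors' deposited table and 78.35-fold enrichment. There, H3K27me3 from 26959200 to 26975199 had a log2 of 3.22 in the authors' deposited table. The female-active domain with the greatest span was on chromosome 5, from 122306148 to 122510423. Its lead H3K4me3 peak, from 122466239 to 122470076, had a log2 of -3.90 in the authors' deposited table, and a male H3K9me3 island from 122451200 to 122465999 had 1.92.

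**Figure D3:**
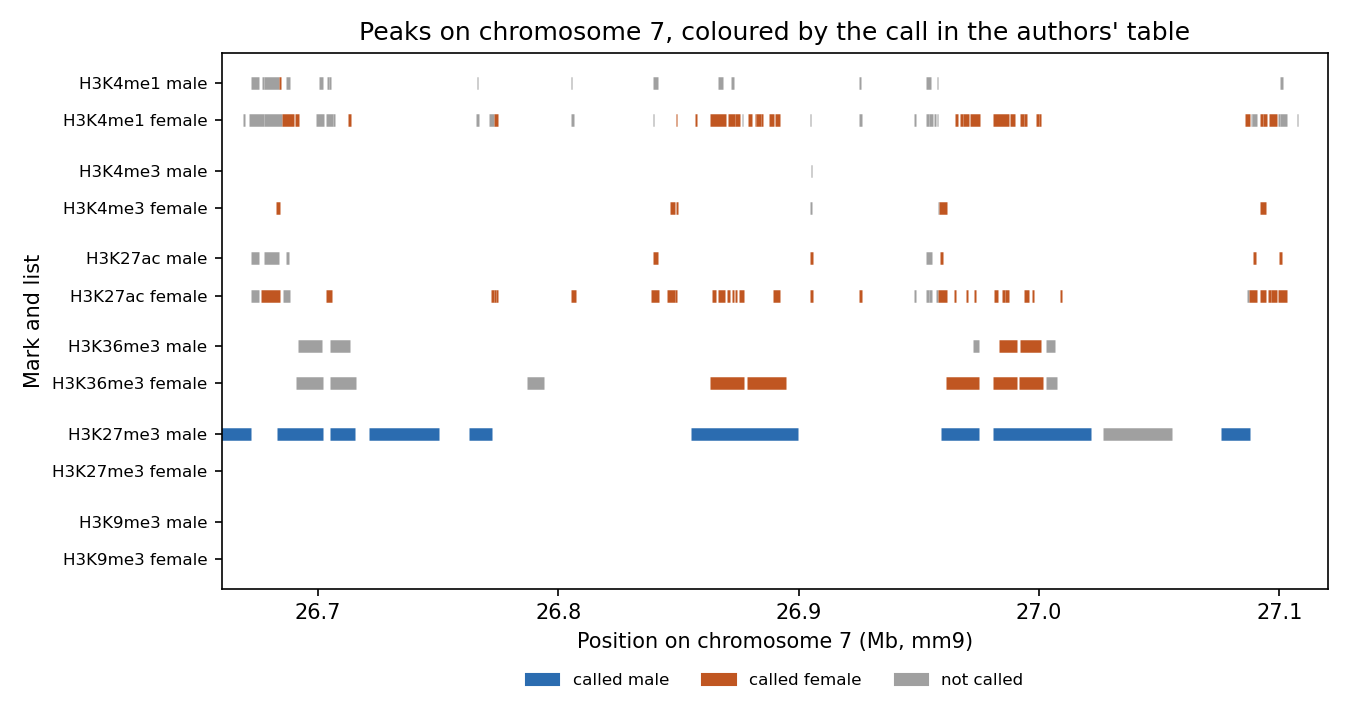
Peaks of the 6 marks in the male and the female list (rows) along chromosome 7 (horizontal axis, Mb, mm9), coloured by the call in the authors' deposited table. Female calls of the active marks stand above male H3K27me3 islands, 9 of which were called male. The female H3K27me3 list and both H3K9me3 lists have no peak in this window.

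Male-active domains looked different, because most lacked H3K27me3 in both sexes. On chromosome 4 from 102999181 to 103176599, 13 H3K4me1, 1 H3K4me3, 6 H3K27ac and 7 H3K36me3 peaks were called male. Its H3K27ac peak from 103052689 to 103071596 held 5055 reads, with a log2 of 3.004 in the authors' deposited table. On chromosome 15 from 4667434 to 4787415, the male-only H3K4me3 peak had a log2 of 3.21 and the H3K36me3 island from 4678200 to 4691799 had 1.85, both in the authors' deposited table. Chromosome 14 from 66263600 to 66409472 and chromosome 7 from 94372576 to 94548999 were male-active in all 4 marks as well.

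The male-active domain with the most called peaks, 46 counted over both lists, was on chromosome 2 from 77707353 to 77898741. It was also the 1 male-active domain with female H3K27me3 calls. Its 5 male H3K36me3 islands had log2 ratios between 3.25 and 3.70 in the authors' deposited table, and they took the 5 highest places among called male H3K36me3 islands. H3K27me3 went the other way, with called log2 values of -1.08, -1.42 and -1.69 in the authors' deposited table. These account for 3 of the 8 female-biased H3K27me3 regions in the genome. H3K9me3 islands lay over the same pieces with a median log2 of 0.00 in the authors' deposited table. Edges of the pieces were shared between marks, and control reads were dense there, at 33.0 per kb against a median of 10.3 over the male H3K36me3 list.

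**Figure D4:**
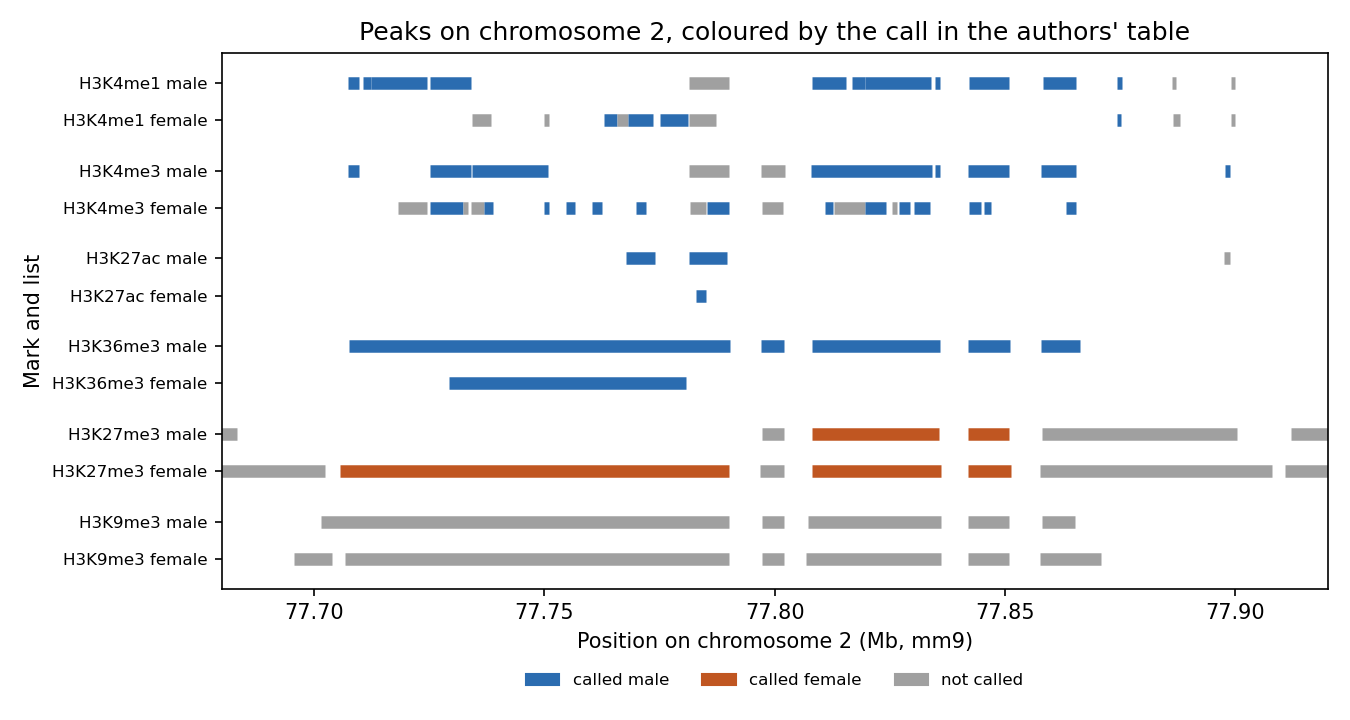
Peaks of the 6 marks in the male and the female list (rows) along chromosome 2 (horizontal axis, Mb, mm9), coloured by the call in the authors' deposited table. Male calls of the active marks and female calls of H3K27me3 share pieces of this segment, H3K27ac calls lie in the first piece alone, and H3K9me3 has no call.

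Biased regions of several active marks overlapped in the same direction, and female-biased regions of the 4 active marks overlapped male-biased H3K27me3. Of 772 male-biased H3K27ac regions, 351 (45.5%) overlapped male-biased H3K4me1 regions and 6 overlapped female-biased ones, against a redraw median of 44 for the first. Of 1220 female-biased H3K27ac regions, 201 (16.5%) overlapped female-biased H3K4me1 and 126 (10.3%) overlapped male-biased H3K27me3, with redraw medians of 28 and 8. Of 86 female-biased H3K36me3 regions, 38 (44.2%, 95% interval 33.5 to 55.3) overlapped male-biased H3K27me3, against a redraw median of 1. The counts were 27 of 244 for female-biased H3K4me3 and 140 of 3406 for female-biased H3K4me1. On the male side there was little to meet. There, 2 of 772 H3K27ac and 3 of 142 H3K36me3 regions lay on female-biased H3K27me3, all in the chromosome 2 segment described above. The overlap counts given so far, except the 6, exceeded every one of the 200 redraws. For the 2 and the 3 on female-biased H3K27me3, this came through that 1 segment alone. Over overlapping regions, the ratios in the authors' deposited table had a Pearson correlation of -0.494 and a Spearman correlation of -0.279 between H3K27ac and H3K27me3 (4927 regions), and of 0.364 and 0.258 between H3K4me1 and H3K27ac (45469 regions). Between H3K36me3 and H3K27me3 the correlations of the ratios in the authors' deposited table were -0.502 and -0.247 (2011 regions). H3K4me1 and H3K36me3 met at biased regions, male with male in 46 and female with female in 48 (highest redraws 12 and 8), against 5 and 2 in opposite directions. Over all their overlapping regions the ratios in the authors' deposited table had correlations of only 0.0719 and -0.0431. Male-biased H3K27me3 overlapped female-biased H3K4me1 in 56 of 162 regions and male-biased H3K4me1 in 16, against highest redraws of 13 and 14. At male-biased H3K4me1 regions the H3K27me3 ratio in the authors' deposited table was above 0 in 56.0% of 979 cases, against 60.2% of 988 at female-biased and 38.7% of 14502 at unbiased ones. These are correlations across regions, among 15 pairs of marks, and regions are not independent replicates.

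Presence and absence gave some of these pairings, with smaller margins. Female-only H3K27ac peaks overlapped male-only H3K27me3 islands in 186 of 4451 cases (4.18%), against a redraw median of 76 and a highest redraw of 96. For female-only H3K36me3 the count was 54 of 1332 (4.05%), against 14 and 24. Male-only H3K36me3 islands overlapped female-only H3K27me3 islands in 106 of 4900 cases (2.16%), with a redraw median of 61 and a highest redraw of 77. Male-only H3K27ac stayed within its redraws, with 175 peaks on female-only H3K27me3 islands against a median of 160 and a highest of 186. The H3K36me3 pairs were not limited to opposite sexes: male-only H3K36me3 met male-only H3K27me3 in 44 cases (redraw median 31, highest 43), and female-only met female-only in 23 (14 and 25). Same-sex overlap was largest between H3K27ac and H3K4me1, at 1031 of 8688 male-only (11.9%) and 829 of 4451 female-only H3K27ac peaks (18.6%), with redraw medians of 576.5 and 526.5. Male-only and female-only H3K4me3 peaks met same-sex-only H3K4me1 peaks in 55 of 1435 and 208 of 3485 cases, at percentiles of 100 and 18.5 among redraws.

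Promoter-type chromatin was active in most places in both sexes. H3K27ac without H3K27me3 marked 80.7% of male (12928 of 16018) and 74.4% of female H3K4me3 peaks (14099 of 18942). H3K27me3 islands overlapped 2316 male (14.5%) and 3151 female H3K4me3 peaks (16.6%) by 1 bp or more. Of these, 1244 male and 1367 female peaks also overlapped H3K27ac. The shares were not compared with random placement, and overlap in liver tissue does not show both marks in the same cells. H3K27me3 without H3K27ac marked 1072 male (6.69%, 6.31 to 7.09) and 1784 female H3K4me3 peaks (9.42%, 9.01 to 9.84). Of 14233 H3K4me3 regions in both lists, 12876 (90.5%) were in the same state in males and females. The H3K27ac and H3K27me3 states were exchanged in few regions, 50 active in males and repressed in females and 11 the other way. Away from H3K4me3, H3K27ac lay on 47.5% of 53935 male and 34.5% of 62129 female H3K4me1 peaks. The female H3K4me3 and H3K4me1 lists were longer than the male ones, with their sex-only peaks towards the weak end. The female H3K27ac list was shorter, with 38306 against 40903 peaks. Such differences in list length can shift all of these shares, and their part was not tested.

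The best-scoring sex-only peaks, named by the fixed rule, differed between marks in how many had a call. All 5 male-only H3K4me3 peaks and all 5 female-only ones were called in their own direction in the authors' deposited table, with log2 values from 2.41 to 4.45 and from -4.49 to -2.29. The first female-only H3K4me3 peaks lay in the domains on chromosomes 7 and 5 described above, on chromosome 1 from 164911421 to 164916218, on chromosome 11 from 115322966 to 115325887, and on chromosome 15 from 60750052 to 60752886. The 5 male-only H3K27me3 islands had log2 values from 1.47 to 2.86 in the authors' deposited table. They lay on chromosome 3 from 98670800 to 98703199 and from 98710000 to 98807599, on chromosome 5 from 122365600 to 122425999, and in the group on chromosome 7. The 5 female-only H3K27me3 islands had log2 values from -1.15 to -0.03 in the authors' deposited table, and only the first 2 were called female. The 5 female-only H3K36me3 islands, on chromosomes 7, 19, 10, 19 and 5, had log2 values from -2.21 to -1.30 in the authors' deposited table. In contrast, the first male-only H3K4me1 peak, on chromosome 5 from 121011708 to 121020267, had a log2 of -0.37 in the authors' deposited table despite rank 22 of its list. The first female-only H3K27ac peak, on chromosome 6 from 115620428 to 115629233, had 0.13 in the authors' deposited table. The first male-only H3K9me3 island, on chromosome 11 from 3019600 to 3100399, had a relative IgG density of 20.6. The first female-only one, on chromosome 12 from 89327600 to 89337999, had a density of 0 and a log2 of -1.47 in the authors' deposited table.

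H3K27me3 and H3K9me3 also differed between the sexes by chromosome. On chromosome 18, H3K27me3 covered 14.5 Mb in males and 9.05 Mb in females, a ratio of 1.601, while the other autosomes ranged from 0.913 to 1.215. The median log2 of shared H3K27me3 islands in the authors' deposited table was 0.16 on chromosome 18 and 0.02 for the median of the other autosomes, which reached 0.10. Chromosome 18 was also highest, by less, for H3K4me1 (0.14, others to 0.13), H3K4me3 (0.12, to 0.11) and H3K9me3 (0.12, to 0.11) in the authors' deposited table. It was lowest for H3K36me3 (-0.038, others down to -0.023) and within the range of the others for H3K27ac (-0.074), per the authors' deposited table. H3K9me3 covered more in males on chromosomes 19 (3.09 against 1.49 Mb), 18 (4.425 against 2.41 Mb) and 11 (8.95 against 7.86 Mb). Over all autosomes the female list covered more, 223 against 176 Mb, with a ratio of 0.553 on chromosome 1. That list also held more reads inside islands. In the authors' deposited table biased H3K9me3 regions were nearly even, 373 male and 396 female, and regions in both lists had a median log2 of 0.003. H3K36me3 and H3K27ac showed ratios within 0.962 to 1.01 and within 1.097 to 1.19 on every autosome.

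**Figure D5:**
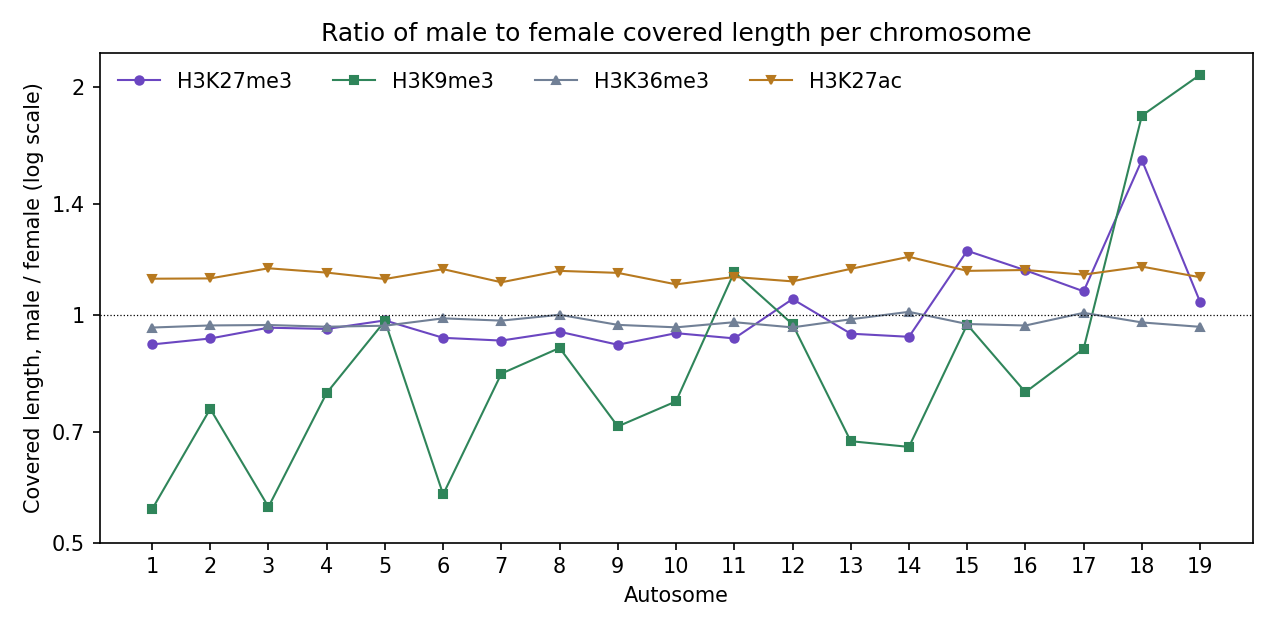
Ratio of male to female covered length (vertical axis, log scale) on each autosome (horizontal axis) for 4 marks. H3K27me3 reaches 1.601 on chromosome 18 and H3K9me3 reaches 2.08 on chromosome 19, and the H3K36me3 and H3K27ac lines stay nearly flat.

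Background in the male IgG library was near the genome average at most peaks. The median relative density was 1.11 in male-only and 1.03 in shared male H3K4me1 peaks, and 0.773 in female-only and 1.02 in shared female ones. It was 1.22 in male-only and 0.996 in shared male H3K27me3 islands, against 1.01 in random regions of the same widths. H3K9me3 islands lay below average, at 0.836 for male-only and 0.970 for female-only islands.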

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

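The tests of opposite signs and of control reads, on chromosome 2 and at the female-active domains, and of an offset of the ratios between the pools, were chosen after the result was seen. So was the decision to use the counting interval of the IgG value, and to let a single IgG library exclude nothing unless the control of the island lists goes with it. Under the rule first written, the IgG value on chromosome 2 below would have counted against extra copies.

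Reads of the IgG library on the X chromosome are listed here because they lie in data outside the comparisons, as none of the peak lists cover it. They numbered 372414, at a density of 0.510 of the autosomal mean, the lowest of the chromosomes in the file. The library is male, so the cells carry a single X chromosome. Local enrichment along it was not tested.

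Male-biased H3K27me3 at female-active domains was found at 23 of 57 domains (highest random placement 2). The reverse was found at 1 of 69 (highest 0), where only 8 female-biased H3K27me3 regions existed to be met. That 1 was the chromosome 2 segment weighed below, and without its H3K27me3 calls the count was 0. Regions in both lists had a median log2 of 0.026, against 1.465 over the 34 domains with islands, and 23 domains kept a male call after centring. This argues only against an offset common to all islands. The straight-line correction for GC content was small too, at -0.0125 log2 per percent GC, and 23 domains kept a male call. It argues only against a straight-line relation of that size. How the deposited ratios were normalised is not given, so other differences between the pools were not tested. High background was argued against by 2 measures. The median IgG density in these islands was 1.12 times the autosomal mean, under the bound of 1.5 set beforehand. Control reads lay at 1.102 times the list median (quartiles 1.001 to 1.23). The libraries behind that control are not given, so the 2 measures may not be independent. The codes in the sample titles, whose meaning the labels do not give, are shared between the sexes for every mark but H3K27me3, so for this mark sex itself, the animals pooled and any batch such a code marks cannot be told apart.

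The male excess of H3K27me3 on chromosome 18 was weighed against technical explanations. For GC content bias of the pools, 99.0% of the shift of the median log2 ratio remained after a straight-line correction. The ratios fell by only 0.0124 log2 per percent GC, and GC content was 42.6% on chromosome 18 against 41.6% elsewhere. A correction this small could hardly move the shift, so this argues only against a straight-line relation of that size. Weak islands near the calling threshold were argued against, because the ratio of covered length was 1.67 in the better-scoring 50% of both lists, where the other autosomes lay between 0.851 and 1.21. Shared regions on chromosome 18 also had the highest median log2 of all autosomes in H3K4me1 (0.14), H3K4me3 (0.12) and H3K9me3 (0.12), by small margins. They had the lowest in H3K36me3 (-0.038), and in H3K27ac (-0.074) they lay within the range of the other autosomes. Sex itself, the animals pooled and any batch marked by the title codes, none of which the male and female H3K27me3 libraries share, may each still account for it and were not tested.

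The segment on chromosome 2 from 77707353, where 4 active marks were male-biased and H3K27me3 female-biased, may reflect a difference in copies between outbred animals. Control reads lay at 3.20 times the median of the male H3K36me3 list, as extra copies relative to mm9 would give, but both sexes shared that control. The IgG library gave 1.44 times the autosomal mean (95% interval 1.35 to 1.545, counting error only), a value below the bound of 1.5 set beforehand with an interval that reaches it, so extra copies cannot be told apart from none. A single difference in copies between the sexes shared by all marks was argued against, because 1 mark, H3K27me3, had calls of the opposite sign. Different animals behind each mark, and sex itself, stay open as untested.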

How the results depend on the processing

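No paired analysis was possible because the peak lists are pooled per sex, and no test between animals was run. Settings on biased regions, domains, GC content and false discovery rate were chosen after seeing the data. Leaving out replicates, gene-level alternatives and shares on the X chromosome were not run, and leaving out sex chromosomes removed no peak. For moved counts the cause was not tested, except that a stricter threshold counts fewer peaks by construction. In the better-scoring 50% of both lists, male-only and female-only peaks numbered 6056 and 11793 (H3K4me1), 185 and 1454 (H3K4me3), 3260 and 1521 (H3K27ac), 2518 and 261 (H3K36me3), 1720 and 2007 (H3K27me3), and 2108 and 5353 (H3K9me3). For better-ranked peaks against the whole other list they were 1351 and 2674, 4 and 26, 408 and 136, 302 and 45, 653 and 761, and 1534 and 4170, in the same order. With a false discovery rate of 5% or less they were 3512 and 5901 (H3K4me1), 90 and 451 (H3K4me3), and 2446 and 827 (H3K27ac). With the longer list shortened, female-only H3K4me3 peaks numbered 1356 and female-only H3K9me3 islands 5508, and H3K36me3 had 1900 male-only and 3294 female-only islands. Requiring that 50% of a peak be covered gave 2540 female-only H3K36me3 islands, and merging peaks within 1 kb gave 15428 female-only H3K4me1 peaks. Leaving out top IgG windows kept all 12 counts within 1.5 times, as did centring the ratios for all 12 counts of biased regions. At a log2 ratio of 1.5 or more, male-biased and female-biased regions numbered 2130 and 876 (H3K4me1), 302 and 106 (H3K4me3), 270 and 381 (H3K27ac), 36 and 33 (H3K36me3), 57 and 1 (H3K27me3), and 33 and 47 (H3K9me3). Correction for GC content left 4105 male-biased H3K4me1 regions, and 183 male-biased and 212 female-biased H3K9me3 regions. It also takes out the offset of shared peaks in each list, and the 2 parts were not separated. Calls in peaks absent from the other list left 488 male-biased and 160 female-biased H3K4me3 regions. With at least 2 active marks there were 545 male-active and 365 female-active domains, 42 of the latter with a male H3K27me3 call and 1 of the former with a female one. Gaps of 10 and 50 kb gave 23 and 21 female-active domains with a male H3K27me3 call. Among the values outside these counts, 9 of 26 overlap and state percentages stayed within their counting intervals, the other 17 did not, and 24 of 24 IgG medians stayed within their quartiles when duplicate reads were counted once. Sequencing depth itself is not given for the peak lists, and what it limits was not tested.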

Other observations

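The tests of relations with GC content given here were chosen after the data were seen, and no explanation was tested. Across regions in both lists, the log2 ratios of male over female fell with GC content for H3K4me1 (Pearson -0.383, Spearman -0.408), H3K27me3 (-0.356 and -0.374) and H3K4me3 (-0.240 and -0.250). They rose for H3K36me3 (0.206 and 0.223) and H3K9me3 (0.203 and 0.174), and showed little relation for H3K27ac (0.0155 and 0.0266). For H3K4me1 the median log2 was 0.32 in the 25% of regions with the lowest GC content and -0.12 in the 25% with the highest. Regions are not independent replicates.

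H3K9me3 and H3K4me1 moved in opposite directions in a small share of regions. Of 3406 female-biased H3K4me1 regions, 51 (1.497%) overlapped male-biased H3K9me3, against a redraw median of 13 and a highest redraw of 23, and 1 overlapped female-biased H3K9me3. Of 6412 male-biased H3K4me1 regions, 23 (0.359%) overlapped female-biased H3K9me3, against 5 and 13, and 3 overlapped male-biased H3K9me3. Over 4522 overlapping regions the ratios of H3K4me1 and H3K9me3 had a Pearson correlation of -0.253. The overlap was not counted again after correction for GC content and list offset, which left 183 male-biased and 212 female-biased H3K9me3 regions. The ratios of these marks run in opposite directions with GC content.

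Some of the highest H3K27me3 ratios lay where background was dense. Of 160 male islands called male, 14 had a relative IgG density of 2 or more, up to 9.04 on chromosome 17 from 36617600 to 36622399, and 0 of these 14 lay in a female-active domain. The remaining female-biased H3K27me3 regions, 5 outside chromosome 2, had log2 ratios between -1.29 and -1.01. They lay on chromosome 11 from 116599600 to 116620799, chromosome 12 from 98170800 to 98174799, chromosome 17 from 36289200 to 36303599, chromosome 19 from 22922000 to 22924399 and chromosome 8 from 23725200 to 23729599.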
